A study of Mus musculus with 115 samples.

How the data were processed

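RNA sequencing libraries were made from striatum punches of 23 F2 mice, with the left and right punches of a mouse pooled, using oligo-dT selection and paired-end reads, per the labels' protocols. Each library was sequenced in 3 runs and on 5 lanes in all, which gave 115 files. The values are whole-number read counts per Ensembl gene, not normalized, as deposited by the authors. FastQC and TopHat2 2.1.1 are named in the submitters' processing notes. The counting program, the genome build, the gene annotation and the use of strand in counting are not given in the sources used here. Every file holds the same 22020 gene identifiers. Of these, 21844 matched identifiers of the GENCODE annotation of GRCm38 used here for symbols and positions, and 2937 genes had no count in any file. No row without a gene name was present.

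The labels give the sex, the age in days, the cage and the genotypes at 90 single-nucleotide markers of every mouse, coded 0, 1 or 2. They give neither the positions of the markers nor the substrain that each code stands for. All changes are therefore given per unit of the code, written below as per allele. At the 4 markers that come last in the labels, no male had genotype 1 and no female had genotype 2, as X-linked markers would give. At an X-linked marker a male coded 2 would carry 1 copy, so a change there is not per copy.

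The mouse was the replicate. Counts of the 5 files of a mouse were summed, after the files had been compared. All 115 files correlated best with another file of their own mouse, over log2 counts scaled to library size (CPM). Counts of the 5 files of a mouse scattered slightly more than sampling alone gives, with a chi-square of 1.21 to 1.39 per degree of freedom. Mouse sums ranged from 30797436 to 35048396 counts, with a median of 33424379. Single files held 3217302 to 11795121 counts.

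Genes with a CPM of at least 0.5 in at least 6 mice were tested, which left 14841 genes. Tests used edgeR 4.0.16 (quasi-likelihood F test after TMM normalization) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype map fitted each of 87 markers with at least 20 genotyped mice as an additive term beside sex and adjusted over all 1291167 gene-marker tests together. Another 3 markers had too few genotypes for the map. Further comparisons concerned the genotype at rs3148686 (beside sex), sex, age (beside sex, per 50 days) and sequencing run (with the mouse as a block). The choice of rs3148686 rested on prior knowledge of the study, and the labels name no marker of the mapped locus. Standard errors were the size of the log2 change divided by the square root of F. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation. There were 27 lists fixed before the data were examined and 2 lists added afterwards.

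The rule for named genes was also fixed before the data were examined. For the map it took the 25 genes with the smallest adjusted p and every tested gene of the lists of known substrain differences and of locus candidates. For sex and age it took up to 12 called genes per direction with a mean log2 CPM of at least 0, with all tested Y-linked genes and X-linked genes that escape inactivation for sex. For sequencing run it took up to 3 genes with the smallest p, and for each list past the threshold up to 4 members. Other genes named in the text were chosen after their values were seen. The comparison at rs6341208 as a set of its own was likewise added after the map had been seen.

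The steps were tested on simulated counts for the 14841 genes, drawn from the real means, dispersions and library sizes with 200 changed genes. In the simulated map, edgeR recovered 64.2% of genes with a 1.25-fold change per allele, 88.1% at 1.5-fold and 100% at 2-fold, and 6.15% of its calls were unchanged genes. In the simulated rs3148686 comparison it recovered 73.1% at 1.25-fold and 98.5% at 1.5-fold. For sex the shares were 64.2% and 92.5%, and for age they were 62.7% and 89.6%. These shares hold for 200 changed genes. Where fewer genes change, the adjustment asks for a smaller p, and a smaller share would be recovered. DESeq2 1.42.0, used as an alternative, gave more calls of unchanged genes, from 8.95% of its calls for sex to 14.4% for age. limma-voom over single files with duplicateCorrelation, another alternative, called 509 genes in a simulated sex comparison, of which 334 were unchanged. Of those, 253 lay in the fifth of genes with the highest correlation between files of a mouse, while a single consensus correlation of 0.47 served all genes.

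Alternatives covered the normalization, the filter on low counts, the test, the covariates, the coding of genotype and age, each run alone, the cage as a block and mice left out.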

Results

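Striatal gene expression was measured by RNA sequencing in 23 mice of an F2 intercross between C57BL/6J and C57BL/NJ, as the labels name them. They are closely related substrains of a common laboratory mouse. The striatum is the input nucleus of the basal ganglia. There were 7 females and 16 males, aged 50 to 100 days, of which 9 were at most 65 days old and 14 were at least 93 days old. All mice had received the opioid oxycodone before a hot plate test of heat pain, so no untreated group could be compared. Each mouse carried genotypes at 90 markers. Summed counts per mouse ranged from 30797436 to 35048396, and mitochondrial genes took 9.04% to 10.98% of them.

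The genotype map asked which genes followed the genotype of the mice. In the map, 35 of 14841 genes were associated with at least 1 of 87 markers, in 61 gene-marker pairs at 12 markers. Of the 9 tested genes on a list of known differences between the substrains, 4 passed over the whole map and 5 when adjusted over the list alone. Nnt (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997 in GRCm38), which encodes a mitochondrial transhydrogenase, rose by 0.46 log2 units per allele at rs29235721 (SE 0.02, adjusted p = 8.0e-11). Its expression was 16.6 ± 0.62 CPM with genotype 0 (SD, n = 7), 23.5 ± 1.71 with genotype 1 (n = 10) and 31.6 ± 1.05 with genotype 2 (n = 6). Wdfy1 (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143) rose by 0.56 at rs242608911 (SE 0.05, adjusted p = 1.2e-05), from 27.9 ± 2.51 CPM (n = 6) to 46.8 ± 1.45 (n = 13) and 58.8 ± 8.04 (n = 4). Gabra2 (ENSMUSG00000000560, chromosome 5, 70957597 to 71095849), a subunit of the GABA-A receptor, rose by 0.44 at rs29547790 (SE 0.04, adjusted p = 9.0e-05). It went from 68.4 ± 8.12 CPM (n = 5) to 93.1 ± 6.85 (n = 14) and 123 ± 7.09 (n = 4). Ide (ENSMUSG00000056999, chromosome 19, 37268743 to 37337852), the insulin-degrading enzyme, fell by 0.40 at rs30709918 (SE 0.06, adjusted p = 0.011). It went from 63.6 ± 14.6 CPM (n = 6) to 50.6 ± 6.59 (n = 10) and 35.8 ± 1.44 (n = 6), but the steps were uneven. With genotype 0, male replicate 1 and female replicate 6 were at 80.1 and 84.2 CPM. The others with genotype 0 lay between 51.8 and 57.4 CPM, and genotype 1 ran from 38.8 to 57.0 CPM. With age as a covariate Ide fell by 0.37 (SE 0.06) and did not pass (adjusted p = 0.063). Fgfbp3, at −0.24 per allele (SE 0.05), passed only over the list alone (adjusted p = 0.014). Pttg1, Crb1, Snap29 and Cyfip2 did not pass either way, and the remaining list members had too few counts to be tested.

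**Figure D1:**
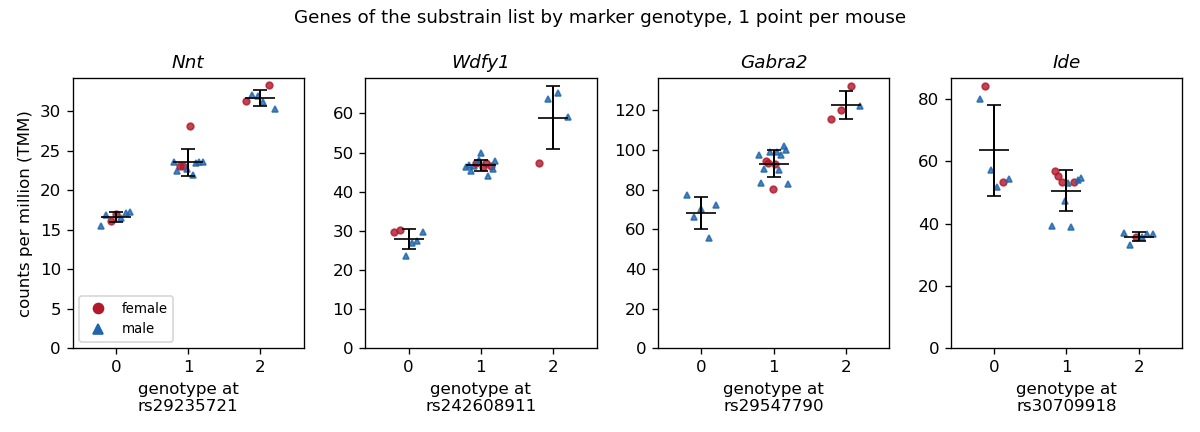
Read counts scaled to library size (CPM, TMM-normalized, y axis, from 0) of Nnt, Wdfy1, Gabra2 and Ide by genotype at the marker with the smallest p (x axis), with 1 point per mouse, females as circles and males as triangles, and the mean ± SD in black. Mean Nnt expression went from 16.6 to 23.5 and 31.6 CPM over genotypes 0, 1 and 2. Mean Ide expression went from 63.6 to 50.6 and 35.8 CPM, with overlap between genotypes 0 and 1.

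Single genes followed several other markers. Cnksr2, a scaffold protein of synapses, and its neighbour Klhl34 lie on the X chromosome. They rose by 0.18 (SE 0.02) and 0.17 (SE 0.02) per unit of the code at rs226776950 (adjusted p = 5.7e-04 and 0.012). This marker behaved as an X-linked one, and there genotype 1 held only females and genotype 2 only males. Gm10600, a predicted gene, fell from 1.39 ± 0.156 CPM with genotype 0 (n = 6) to 0.607 ± 0.164 with genotype 1 (n = 9) and 0.0075 ± 0.0139 with genotype 2 (n = 8) at rs46850777 (adjusted p = 5.7e-04). Ttr, the thyroid hormone carrier transthyretin that is abundant in choroid plexus, rose by 2.81 per allele at rs236603300 (SE 0.41, adjusted p = 0.017). Its counts were low, 2 mice had genotype 0, and with limma-voom its adjusted p was 0.76. Without 1 mouse the change ran from 2.24 to 3.19, and without male replicate 2 or 15 its p was above the largest p called in the map. Frem3 at rs33508711 and Fzd5 at rs246033409 also passed (adjusted p = 0.027 and 0.049), but Fzd5 did not pass with the marker rs51237371, which repeats another, left out. Over the whole map, 63093 pairs had an unadjusted p under 0.05, against 64558 from chance alone.

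The map's largest group of genes followed rs6341208, which was then examined on its own, with 24 lower and 1 higher per allele among 25 genes, by a median of −0.22 log2 units. At this marker 11 mice had genotype 0, 12 had genotype 1 and none had genotype 2. Atf4 (ENSMUSG00000042406, chromosome 15, 80255184 to 80257541), the central transcription factor of the integrated stress response, fell by 0.35 (SE 0.04, adjusted p = 5.7e-04), from 128 ± 9.18 to 100.4 ± 6.70 CPM. Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), which degrades glutathione and is a target of Atf4, fell by 0.61 (SE 0.07, adjusted p = 4.8e-04), from 5.98 ± 0.798 to 3.90 ± 0.298 CPM. Asns, asparagine synthetase, fell by 0.24 (SE 0.03, adjusted p = 0.0070), and the related factor Atf5 fell by 0.29. Nudt3, a diphosphoinositol polyphosphate phosphatase, fell from 282 ± 11.8 to 229 ± 9.51 CPM (log2 change −0.30, SE 0.03, adjusted p = 3.1e-05). The paralogs Bex1 and Bex2 fell by 0.37 (SE 0.04) and 0.27 (SE 0.04). The spliceosome components Snrpd1 and Snrpd3 fell by 0.35 (SE 0.04) and 0.21 (SE 0.03). Mfn2, which fuses mitochondria, fell by 0.19 (SE 0.02). Nabp2, Tspyl4, Ubald1, Gdi2, Fam8a1, Rnf6 and Ptges3 were also lower, by 0.15 to 0.31, and Tsr2 was higher by 0.17. Over all 14841 genes, the mice of the 2 genotypes did not overlap in 16, of which 14 were among the 25. Chance gives this for 1.5e-04% of genes at a single marker, but this marker was picked after the map. The 25 genes lay on 16 chromosomes. The neighbouring marker rs51237371 had identical genotypes, so each of these genes was counted at both markers. With rs51237371 left out, 26 genes passed in the map, 17 of them at rs6341208, and Atf5 was among those that did not. With adjustment within this marker alone, 165 genes passed, 55 higher and 110 lower. Without 1 mouse this count ran from 93 to 278, DESeq2 gave 428 and age as a covariate 385. With the cage as a block, 0 genes passed (smallest adjusted p = 0.32), where 3 of 14 cages held both genotypes and 8 residual degrees of freedom were left. The median change of the 165 was −0.14 without the block and −0.13 with it, and their median SE went from 0.036 to 0.057. However, 17 of 100 maps, of which 99 had exchanged genotypes, had a marker with as many genes by limma-trend. Nnt was itself higher with genotype 1 at rs6341208, by 0.51 (SE 0.10, adjusted p = 0.010 within the marker), at 19.4 ± 3.34 CPM with genotype 0 and 27.4 ± 5.10 with genotype 1. The genotypes at rs6341208 and at the Nnt marker rs29235721 correlated with r = 0.64 over 23 mice. For rs32180662 and rs254201911, which stand beside rs6341208 and rs51237371 in the labels, r with rs6341208 was 0.49 and 0.17. With the genotype at the Nnt marker rs29235721 as a covariate, the change of Nnt was 0.09 (SE 0.04), while all 25 genes kept their direction and at least 0.706 of their size. Their median was −0.22 with and without the covariate, and the median SE went from 0.029 to 0.038. Of the 25 genes, 19 passed within rs6341208, among them Nudt3 at −0.30 (SE 0.04), Atf4 at −0.32 (SE 0.05), Chac1 at −0.60 (SE 0.09) and Asns at −0.22 (SE 0.04), and 30 genes passed in all. The other 6 did not pass, and for each of them the change was smaller and the standard error larger than without the covariate, with Fam8a1 at −0.16 (SE 0.02) before and −0.11 (SE 0.03) after. The list of cortical excitatory neuron genes passed by camera with 12 of 12 changes below 0, of which 4 passed over the list alone (median −0.31, adjusted p = 1.8e-04, adjusted p = 0.65 with an estimated correlation). The list of striatal projection neuron genes passed with 12 of 12 above 0 and no member passing (median 0.13, adjusted p = 0.0046, adjusted p = 0.65 with an estimated correlation). The lists of indirect pathway neurons (7 of 7 above 0, 2 passing over the list alone), ependymal cells (9 of 9, none passing) and immediate early genes (13 of 14, none passing) had camera adjusted p = 0.013, 0.010 and 0.0079, and each had adjusted p = 0.65 with an estimated correlation. The list of 4 Y-linked genes passed as well, with no member passing (median 0.14, adjusted p = 0.0010, adjusted p = 0.47 with an estimated correlation).

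**Figure D2:**
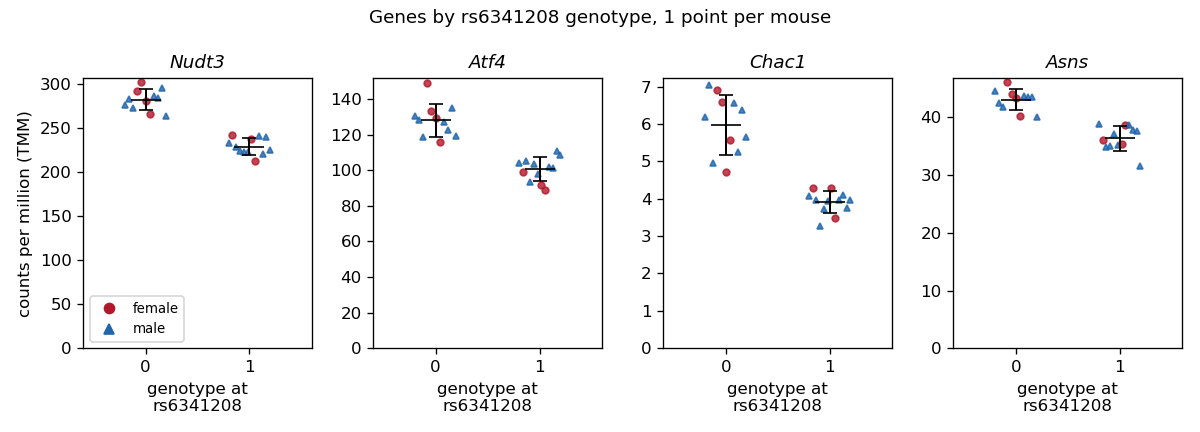
Read counts scaled to library size (CPM, TMM-normalized, y axis, from 0) of Nudt3, Atf4, Chac1 and Asns by genotype at rs6341208 (x axis), with 1 point per mouse, females as circles and males as triangles, and the mean ± SD in black. The 11 mice with genotype 0 lay above the 12 mice with genotype 1 for each of the 4 genes.

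**Figure D3:**
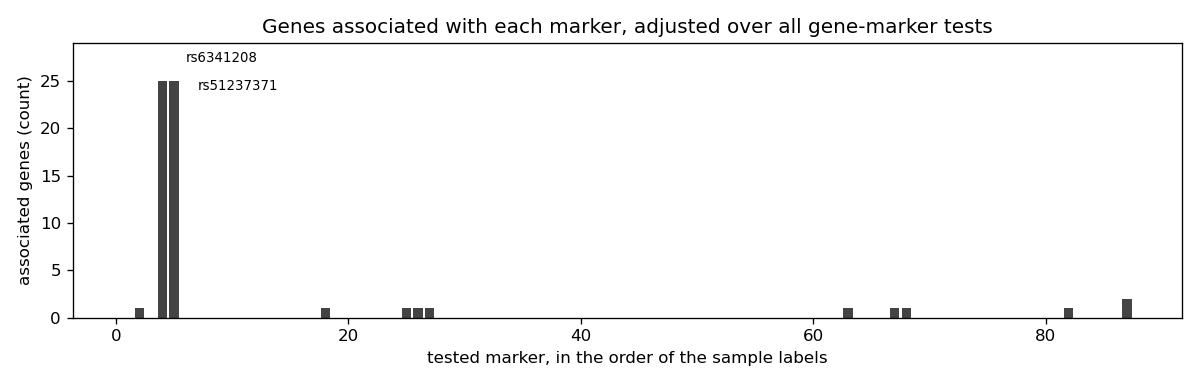
Number of associated genes (y axis) at each of the 87 tested markers in the order of the sample labels (x axis), after adjustment over all gene-marker tests. The bars at rs6341208 and rs51237371 stand at 25 genes each and hold the same mice in each genotype class.

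A further test asked whether genes that followed the same marker lay on the same chromosome. Only 3 markers had more than 1 gene, and 50 of their 52 gene-marker pairs were the 25 genes of rs6341208 counted there and at rs51237371. Of the 52 pairs, 19.2% lay on the chromosome with most genes of their marker, against a median of 17.3% in 10000 permutations of chromosomes (one-sided permutation p = 0.24). With rs51237371 left out, 2 markers and 19 pairs remained, with 31.6% against a median of 21.1% (p = 0.051). The marker beside rs6341208 in this test was rs226776950. Its 2 genes, Cnksr2 and Klhl34, are neighbours on the X chromosome, so both counted toward the share.

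The genotype at rs3148686 was compared because the study mapped a locus for heat pain. No gene passed among 14841 by edgeR (smallest adjusted p = 0.41), and 659 had an unadjusted p under 0.05 against 742 from chance. DESeq2 called 5 genes, of which Cyp2a5, Cyp2g1, Gys1 and Ndn lie on chromosome 7. Cyp2a5 (ENSMUSG00000005547, chromosome 7, 26835305 to 26843548), a cytochrome P450 enzyme with close paralogs that can share reads, was at 0.923 ± 0.654 CPM with genotype 0 (SD, n = 2), 2.26 ± 0.454 with genotype 1 (n = 11) and 3.09 ± 0.645 with genotype 2 (n = 10). Its log2 change per allele was 0.63 (SE 0.13, adjusted p = 0.41 by edgeR and 0.0065 by DESeq2). On the list of 7 locus candidates, which the study chose on these mice and which is no independent evidence, Cyp2a5 alone passed when adjusted over the list alone in the map (adjusted p = 0.036). Ryr1, Pou2f2, Clip3, Sirt2, Actn4 and Ltbp4 did not pass at any marker. All 18 tested genes of the mitochondrial respiratory chain had a change above 0 per allele (median 0.07, camera adjusted p = 6.1e-11), and 3 passed over the list alone. That call was lost with an estimated correlation (adjusted p = 0.21). The examples Ndufs4 and Atp5e had changes of 0.13 (SE 0.03) and 0.20 (SE 0.06). Lists of microglia, striatal projection neurons, astrocytes and striatal interneurons passed in the same direction and were likewise lost (adjusted p = 0.21 to 0.76 with an estimated correlation). Opioid peptides and receptors did not pass (8 genes, adjusted p = 0.43), nor did nociceptive channels and mediators (11 genes, adjusted p = 0.43).

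Females and males differed in 12 genes, 7 higher and 5 lower in females. The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y were at 32.5 ± 1.47, 65.3 ± 6.72, 11.8 ± 1.26 and 26.9 ± 5.73 CPM in 16 males, and at most 0.308 ± 0.240 CPM on average in 7 females. Uba1y, also Y-linked, was low in males at 0.53 ± 0.155 CPM. The X-linked genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x, which escape X inactivation, were higher in females by 0.44 (SE 0.04), 0.43 (SE 0.05), 0.31 (SE 0.03) and 0.51 (SE 0.08), and all 4 passed over all genes and over the list alone. Gm26992, a gene model on the X chromosome (103422010 to 103481705) that overlaps other genes, was at 24.7 ± 4.72 CPM in females and 0.138 ± 0.0563 in males. Its reads cannot be assigned without strand. Of autosomal genes, Hbegf, a growth factor of the EGF family, was higher by 0.29 (SE 0.05, adjusted p = 0.0026). Snai3, a transcription factor, was higher by 0.74 (SE 0.13, adjusted p = 0.013), and its adjusted p was 0.076 without female replicate 1 and 0.067 without female replicate 4. The lists of striatal projection neuron genes (median 0.13), immediate early genes (median 0.29) and cortical excitatory neuron genes (median −0.19) also passed by camera with no member passing, with adjusted p = 0.70, 0.70 and 0.72 with an estimated correlation.

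For age, 3 genes passed. Mice of a cage shared an age, and when ages were exchanged between whole cages, 6 of 100 arrangements (the real one included) had at least 3 genes, so chance was not excluded. Per 50 days, Jun, an immediate early transcription factor, fell by 0.36 (SE 0.06) and Asb4 fell by 1.17 (SE 0.20), while Nfkbia, an inhibitor of NF-kappa B, rose by 0.47 (SE 0.08), each with an adjusted p of 0.027. Jun was at 36.5 ± 2.43 CPM in 9 mice up to 65 days and 30.1 ± 3.39 in 14 mice of at least 93 days. Of 12 circadian clock genes, 8 rose and 1 fell when adjusted over the list alone, and none over all genes. The list passed by camera (adjusted p = 2.3e-08, adjusted p = 0.10 with an estimated correlation). Per2 rose by 0.82 (SE 0.16) and Cry1 by 0.45 (SE 0.10) over the list alone, while Arntl fell by 0.28 (SE 0.11). Of 10 glucocorticoid response genes, 4 rose over the list alone, including Sgk1 at 0.84 (SE 0.16) and Nfkbia (camera adjusted p = 5.6e-06, adjusted p = 0.10 with an estimated correlation). The lists of interferon response, striatal projection neuron and immediate early genes passed by camera with medians above 0, and the cortical excitatory neuron list with a median below 0. No member of these 4 lists passed, and each list had adjusted p = 0.76 with an estimated correlation. Jun, which passed and fell, was not on the list of immediate early genes. The striatal projection neuron list moved up and the cortical excitatory neuron list down at rs6341208, for sex and for age alike. At rs3148686 the cortical list had 2 of 12 changes above 0 and did not pass (camera adjusted p = 0.054). All 4 comparisons used the same mice, and whether these shifts share 1 source was not tested. Without single mice the number of called genes ran from 0 to 61, and DESeq2 called 60, so the count of 3 rested on individual mice and on the test.

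The same libraries differed slightly between sequencing runs. By edgeR with the mouse as a block, 798 genes (5.38%) differed. Over all 14841 tested genes, called or not, the median size of the change was 0.029 log2 units for run 160823 and 0.025 for run 160830, each against 160816. Of the 798 genes, only 9 exceeded 0.5. The smallest p-values belonged to the mitochondrial genes mt-Nd1, mt-Nd5 and mt-Co1, with mt-Nd1 at −0.0052 and 0.044.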

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

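The comparisons in this part followed rules fixed beforehand. A sample far from the others was sought in 59 groups of 4 to 10 mice and found in 5, where chance alone would give about 2.95. Nnt was at 28.1 CPM in female replicate 3, while the other mice with genotype 1 at rs29235721 lay between 21.9 and 23.6 CPM. The same mouse had 0.416 CPM of the Y-linked Kdm5d, against 0 to 0.152 CPM in the other females. Uba1y was at 0.0289 CPM in female replicate 5 and at 0 in the other females. The rule flags any count above 0 in such a group, so this call carries little weight. Snap29 was at 35.2 CPM in female replicate 7 among mice with genotype 2 at rs30709918, where the others lay between 29.5 and 31.4 CPM. Ryr1 was at 45.8 CPM in male replicate 5, against 67.2 to 70.7 CPM in the other mice with genotype 2 at rs238893157. The test of a difference between females and males in the genotype or age effect of named genes passed for 0 of 40 gene effects by edgeR, adjusted over the 40. The smallest unadjusted p belonged to Atf4 at rs6341208 (0.016). The 3 markers left out of the map, with 12, 13 and 12 genotyped mice, gave 0 genes by edgeR, with 156, 392 and 1173 genes at an unadjusted p under 0.05.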

How the results depend on the processing

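Of these alternatives, those at rs6341208, those with cell-type list means as covariates, with rs51237371 left out, with the cage as a block, and with each mouse left out for sex, age, rs6341208 and Ttr by edgeR were chosen after the data were seen; the others were fixed beforehand. No paired analysis was possible because the replicate numbers only name mice and pair none. Mice of a cage shared sex and age, so a cage block could be fitted for genotypes alone, and 3 of 14 cages held both genotypes at rs6341208. With the cage as a block, 0 genes passed at rs6341208. In the map, 29 to 44 genes passed with another normalization, filter, test, covariate or genotype coding, and 26 to 35 of these were among the 35. Run 160816 alone gave 17 genes in 28 pairs, run 160823 alone 17 genes in 27 pairs and run 160830 alone 26 genes in 41 pairs. A single run holds fewer counts per mouse, but whether depth explains this was not tested. Leaving out rs51237371 gave 27 pairs in place of 61, since that marker repeats another. All 37 named map genes kept their direction without any 1 mouse by limma-voom. By edgeR, Ttr at rs236603300 ran from 2.24 to 3.19 and was under the largest p called in the map (2.3e-06) in 21 of 23 fits, with p = 5.1e-06 without male replicate 2 and 2.1e-05 without male replicate 15. The position test kept its outcome without rs51237371 (p = 0.051 in place of 0.24). At rs6341208, DESeq2 gave 428 genes, age as a covariate 385, run 160816 alone 55, run 160823 alone 57, and the genotype at the Nnt marker rs29235721 as a covariate 30 (29 of them among the 165), in place of 165. Without 1 mouse the count ran from 93 to 278, with 93 without female replicate 3, 97 without male replicate 4, 105 without female replicate 7 or male replicate 7, 108 without male replicate 3, 109 without male replicate 16 and 278 without male replicate 12. At rs3148686, DESeq2 called 5 genes and duplicateCorrelation 127, and each other alternative called 0. For sex, DESeq2 called 25 and duplicateCorrelation 776, in each case with all 12 genes of the main comparison, and leaving out 1 mouse gave 11 to 18, with 18 without female replicate 7. On simulated counts most calls of duplicateCorrelation were unchanged genes. For age, DESeq2 gave 60 genes, the list means as covariates 18, run 160816 alone 1, run 160823 alone 4, none of them among the 3, and run 160830 alone and 2 age classes 0. Leaving out 1 mouse gave 0 to 61 genes for age. It gave 0 without female replicates 2 and 7 or male replicates 5, 10, 12, 14 and 16, and 1 without female replicate 5 or male replicate 7. It gave 5 without male replicate 1 or female replicate 3, 8 without male replicate 4, 9 without male replicate 13 or female replicate 6, 12 without male replicate 11, 14 without male replicate 6 and 61 without female replicate 4. With an estimated correlation, 0 gene lists passed for rs3148686, age and rs6341208, and 2 passed for sex. The cause of these changes was not tested, except where stated. Of the candidates at rs3148686, 3 near 0 changed sign, and so did Ryr1. Sirt2 by rs3148686 genotype was at 0.0025 with duplicateCorrelation, 0.0024 without a covariate, 0.013 in run 160816, 0.0094 in run 160823, 0.0080 with the list means, 0.064 with genotype 2 against 1, and −0.012 to 0.053 without genotype 0 replicate 1 or 2. Clip3 by rs3148686 genotype was at 9.1e-04 with duplicateCorrelation, 3.7e-06 in run 160816, 0.0035 in run 160823, 0.017 with the list means, 0.043 with genotype 2 against 1, and −4.0e-05 to 0.029 without genotype 0 replicate 1 or 2. Ltbp4 by rs3148686 genotype was at −0.0088 in run 160823, −0.084 with genotype 2 against 1, and −0.076 without genotype 0 replicate 2. Ryr1 by rs3148686 genotype was at −0.12 (SE 0.09) and at 0.018 with the cage as a block. None of these passed.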

Other observations

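The tests of the integrated stress response list, of age and cage, of the Nnt marker as a covariate, of time of day, and the exchanges between cages were chosen after the results they bear on were seen, and both lists of the first 2 paragraphs were drawn up after the map. Of 35 tested integrated stress response genes, 30 had a change below 0 per allele at rs6341208 (median −0.09). Among the 31 not called in the map, 26 had a change below 0 (camera p = 1.2e-06, p = 2.6e-04 with an estimated correlation), although none of these passed over all genes. Slc7a3, an amino acid transporter, was at −0.41 (SE 0.11), and Sesn2 at −0.23 (SE 0.06). Of 19 tested cytosolic aminoacyl-tRNA synthetase genes, 14 had a change below 0, and Yars, Cars and Nars passed at the marker, at −0.18, −0.20 and −0.18 (adjusted p = 0.0030, 0.0058 and 0.0083). The 16 others gave a camera p of 0.0041, but p = 0.12 with an estimated correlation.

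A hypothesis for the genes at rs6341208 is that lower integrated stress response activity goes with the counted allele. The camera p of the list members not called in the map was 1.2e-06, and 2.6e-04 with an estimated correlation. The list was drawn up after the map and tested in the same mice, so this is no independent evidence. C57BL/6J is known to carry a mutation in an arginine tRNA gene of the brain, which may be a source, but tRNA was not analysed here and the marker's position is not in the labels. With the means of 3 cell-type lists as covariates, 120 genes passed, 84 of them among the 165, and all 25 map genes passed. This argues against cell makeup or dissection as the whole cause. Against age, 385 genes passed with age as a covariate. With the genotype at the Nnt marker as a covariate, the median change of the 25 was −0.224. This is only weak evidence against the Nnt marker as the whole cause. The 25 were picked in these same mice for following rs6341208, which favours that marker in each of these fits. The part of the Nnt marker in the effect stays open, since 19 of the 25 passed then, and 30 genes in all in place of 165. The genotypes at the 2 markers went together (r = 0.64), so the fit separates them only in part. Library batches, the absence of genotype 2 (exact binomial p = 0.0026 against 25%) and cage stay open as well. With the cage as a block 0 genes passed, while all 165 kept their direction. Their median change was −0.13 against −0.14, but it mixes 55 higher and 110 lower genes. This does not decide on cage, since these genes were picked for the pattern and only 3 of 14 cages held both genotypes.

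For Ttr, choroid plexus tissue in some punches stays open. The other 7 choroid plexus genes correlated with Ttr with a median r of 0.39 over 23 mice, from 0.018 to 0.61, and 5 of them had under 500 counts over all mice. Their median change per allele at rs236603300 was 0.24, from −0.18 to 0.48, far below the 2.81 of Ttr. A change of Ttr alone stays open too, since Kl, with 2254 counts, was at 0.48 (SE 0.16, unadjusted p = 0.0072) and Kcne2 at 0.36 (SE 0.17, unadjusted p = 0.045).

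For age, time of day or stress at collection may move circadian clock and glucocorticoid genes, but the smallest adjusted p of both lists was 0.10 with an estimated correlation, which leaves this and an effect of age itself open.

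Exchanges of labels gave smaller results than the real ones in most cases. With whole genotypes exchanged within sex, 1 of 100 maps, the real one, had as many genes by limma-trend, at 38 against at most 3. For sex, 4 of 100 splits had at least 12 genes by edgeR, and the highest other had 39. With cage mates kept together, it was 3 of 100, and the highest other had 60. For age, 1 of 100 exchanges between mice had at least 3 genes, the highest other having 2. Cage mates shared an age, however, and when ages were exchanged between whole cages, 6 of 100 had at least 3, the highest other having 24. For sequencing run, 1 of 21 had at least 798, the highest other having 4. Chance is excluded at a share of 0.05 for sex and run, but not for age. For the map it is excluded only under exchanges of single mice, which took no account of cages. Of the 35 map genes, 25 followed rs6341208, where 0 genes passed with the cage as a block and 8 residual degrees of freedom. Chance could not be excluded for the count of 165 either, since 17 of 100 maps by limma-trend (the real one included) had a marker with as many, and the highest other had 1100, which may come from a structure of the samples that was not tested. For each of 87 markers, the chromosome with the smallest hypergeometric p for genes with an unadjusted p under 0.01 was taken, and p was adjusted over chromosomes and markers. It passed for rs30522453 (chromosome 6, 53 genes against 28.96 expected, adjusted p = 0.026). For rs3148686 it did not (chromosome 7, 18 genes against 9.63, adjusted p = 0.93). There the unadjusted hypergeometric p was 0.0072, the smallest of 20 chromosomes. This comparison was added after the map.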
